A study of Drosophila melanogaster with 3 samples.

How the data were processed

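Chromatin immunoprecipitation followed by sequencing was carried out on Kc167 cells, a Drosophila melanogaster line derived from embryos and grown in serum-free medium. The 3 libraries were made with 3 antibodies, 1 library per antibody. One antibody was raised against the 2.2 isoform of Mod(mdg4), one against the BTB domain that the Mod(mdg4) isoforms have in common, and one against L(3)mbt. Per the labels' protocols, cells were fixed with formaldehyde, chromatin was sheared by sonication, complexes were collected on protein A beads, and the adaptor-ligated DNA was amplified and size-selected on a gel. The control reads came from an earlier study of the same cell line, per the series' design text, and were not analysed here.

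The authors deposited 1 peak list per library, with the sequence name, start, end, a peak name and a score for each peak. Reads were aligned with Bowtie 0.12.5, per the submitters' processing notes. The peak names have the form that MACS writes, per the files, which hold 1 list for each library. The version and settings of the caller are not given in the sources used here. The score in the deposited lists is the peak caller's own value for a peak and ran from just above 100 in each list. Many peaks carried exactly 3100.00 and a few carried more. Whether a score above 3100 marks a stronger peak than 3100.00 is not given in the sources used here. All peaks at or above 3100 were therefore treated as tied, and scores were used only as ranks within a list. The genome build is not named in the sources used here. The sequence names in the files, such as 2LHet and Uextra, are those of release 5 of the Drosophila assembly. U and Uextra hold sequence that was not placed on a chromosome, and Uextra is a concatenation of small scaffolds. The gene table at hand belongs to a later release, so peaks are given by position only. The planned comparisons with transcription start sites, gene lists and DNA motifs were not run for the same reason. Positions are printed counting from 1.

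The files give peaks and not reads, so the sequencing depth is unknown and no level of binding was compared between libraries. With 1 library per antibody, no difference between libraries has a replicate check. Each p-value below concerns the positions or ranks of peaks in these lists, not repeat cultures, and peaks are not independent replicates. Intervals are 95% intervals (Wilson for shares, exact conditional for odds ratios) and cover counting error only. If the 3 lists share 1 control, part of their overlap may come from it. This was not simulated, since it needs the reads.

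A peak was called shared when it had at least 1 bp in common with a peak of another list. The share was compared with 1000 random placements of the same peaks, keeping widths and the sequence each peak lay on, by a one-sided permutation test whose smallest p is 0.001. The length of a sequence was taken as the highest peak end in any of the 3 lists. Placements used all of it, including any parts where no peak can be called. Such parts would lower the random shares and lengthen the random distances. L(3)mbt at BTB peaks with and without 2.2 was compared by a two-sided Fisher's exact test. Ranks of shared and unshared peaks were compared by a two-sided permutation test of the difference in medians, with 100000 resamples and Benjamini-Hochberg adjustment over 6 contrasts. Distances to the nearest peak were compared with 1000 random placements. Sites of all 3 lists were joined where peaks overlapped. Results were also set out for the 5 long arms (2L, 2R, 3L, 3R and X) alone. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6.

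The main tests, the alternatives and the rule for named peaks were fixed before the data were examined. The shares by score band, the classes of joined sites and the odds ratios for single sequences were not part of that plan. The rule took the 10 highest scores in each list, and the 5 highest mean ranks among BTB peaks held by all 3 lists, by 2.2 without L(3)mbt, and by L(3)mbt without 2.2. The alternatives were a stricter overlap of at least 50% of the shorter peak, peak centres within 200 bp, peaks set to 400 bp around their centres, the upper 50% of each list by score, the 5 long arms alone, and placements shifted by 5 to 50 kb. The code was tested on simulated data of the same sizes. Of 100 randomly placed 2.2 lists tested against BTB, 3 gave a p below 0.05. With 1418 of 2846 peaks of the 2.2 list planted on BTB peaks, the number found shared was 100.5% of that expected, and for 1674 of 3352 L(3)mbt peaks it was 99.5%. An odds ratio of 0.4 set over 7621 BTB peaks was recovered as 0.389 (0.347 to 0.435). Of 100 rank tests with no difference, 6 gave a p below 0.05, and a difference of 10 points set in 2846 ranks was recovered as 8.23. In the simulations the status of a peak was independent of its neighbours and ranks held no ties, unlike in the real lists. The null lists were placed by the same rule as the test's own placements. These checks cover the code and not how well those assumptions hold.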

Results

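Mod(mdg4) is a family of chromatin proteins that share a BTB domain and differ in their C-terminal parts, and its 2.2 isoform is the partner of Su(Hw) at the gypsy insulator. L(3)mbt is a chromatin protein with MBT repeats, known as a brain tumour suppressor. Their binding sites in Kc167 cells were recorded as 3 lists of ChIP-seq peaks, from 1 library each. The 2.2 antibody gave 2846 peaks with a median width of 1172 bp, which covered 4.06 Mb. The BTB antibody, which recognises all isoforms, gave 7621 narrower peaks (median 628 bp, 5.78 Mb in all). L(3)mbt gave 3352 peaks (median 1303 bp, 5.49 Mb in all). Peaks at or above the score of 3100 made up 25.6% of the 2.2 list (95% Wilson interval 24.04 to 27.25%), 25.7% of the BTB list (24.7 to 26.7%) and 1.52% of the L(3)mbt list (1.16 to 1.99%). Depth is unknown, and it acts on the number, width and score of peaks, so these figures do not rank the proteins by binding.

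The peaks of all 3 proteins lay mainly on the long chromosome arms. The arms 2L, 2R, 3L, 3R and X held 77.1% of the 2.2 peaks (75.5 to 78.6%), 80.6% of the BTB peaks (79.7 to 81.5%) and 86.2% of the L(3)mbt peaks (85.0 to 87.3%), against 70.8% of the length spanned by peaks. On these arms there were 18.5 peaks of 2.2, 51.8 of BTB and 24.4 of L(3)mbt per Mb. The X chromosome, which spanned 13.3% of the length, held 15.2% of the 2.2 peaks (13.9 to 16.5%), 15.7% of the BTB peaks (14.9 to 16.5%) and 16.7% of the L(3)mbt peaks (15.5 to 18.0%). X and the autosomal arms held 19.3 and 18.3 peaks per Mb for 2.2, 53.4 and 51.4 for BTB, and 24.98 and 24.21 for L(3)mbt. The arm 2L was the sparsest of the long arms for each protein, with 15.8, 44.3 and 19.99 peaks per Mb in the same order. Placed heterochromatin was poor in peaks, at 4.57 per Mb for 2.2, 8.57 for BTB and 2.29 for L(3)mbt. How much of it reads can be aligned to was not analysed, so few peaks need not mean little binding. Chromosome 4 held 7, 35 and 9 peaks. The unplaced sequences U and Uextra held 21.2% of the 2.2 peaks (19.8 to 22.8%), 17.9% of the BTB peaks (17.1 to 18.8%) and 12.9% of the L(3)mbt peaks (11.8 to 14.1%), against 23.2% of the length. The median score there was 166 against 1080.3 on the long arms for 2.2, 252 against 870.3 for BTB, and 216 against 313 for L(3)mbt.

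The first comparison asked how far the sites of the 2.2 isoform lie within those of all isoforms. Most did. Of the 2846 Mod(mdg4)2.2 peaks, 2341 met a BTB peak (82.3%, 80.8 to 83.6%), which is 8.35-fold the mean of 9.86% over random placements (one-sided permutation test, p = 0.001, the smallest the 1000 placements can give). On the long arms the share was 91.8% (90.5 to 92.8%), and on Uextra it was 49.5% (45.4 to 53.7%). The 2.2 peaks with BTB ranked higher in the 2.2 list than those without, at median percentiles of 58.8 and 18.2 (two-sided permutation test, adjusted p = 1.2e-05). By score, 70.5% of the 2.2 peaks on these arms scoring 100 to 200 met BTB (65.7 to 74.8%), 85.7% of those at 200 to 500 (82.1 to 88.7%), 99.0% of those at 500 to 3100 (97.9 to 99.5%), and all 715 peaks at or above 3100 (99.5 to 100%). With peaks set to 400 bp over all sequences, some peaks at or above 3100 met no BTB peak. That setting misses a BTB peak well off the centre of a wide 2.2 peak. The centres of shared peaks lay close together, with a median distance of 44 bp (interquartile range 17.5 to 118.5 bp) against 513 bp for peaks that met by random placement (permutation p = 0.001). In the opposite direction, 2533 of the 7621 BTB peaks met a 2.2 peak (33.2%, 32.2 to 34.3%), so 5088 BTB peaks had no 2.2 peak. BTB peaks with 2.2 ranked higher in the BTB list than those without, at median percentiles of 63.5 and 43.2 (permutation test, adjusted p = 1.2e-05).

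The second comparison set L(3)mbt against Mod(mdg4). Of the 3352 L(3)mbt peaks, 2060 met a BTB peak (61.5%, 59.8 to 63.1%), 5.53-fold the random mean of 11.1% (permutation p = 0.001). Among peaks on the long arms this share was 66.3% (64.5 to 68.0%), and it went from 53.0% of the L(3)mbt peaks scoring 100 to 200 (49.7 to 56.3%) to 89.4% of the 47 peaks at or above 3100 (77.4 to 95.4%). L(3)mbt peaks with BTB ranked higher in their own list than those without, at median percentiles of 57.3 and 38.9 (permutation test, adjusted p = 1.2e-05). With peaks set to 400 bp these were 53.3 and 46.3 (permutation test, adjusted p = 2.4e-05), and 0.956% of the peaks with BTB and 2.09% of those without were at the score ceiling. By that setting peaks at the ceiling met BTB less often than the rest, unlike with an overlap of 1 bp. With 1 bp, 42 of the 51 L(3)mbt peaks at the ceiling met BTB (82.4%). The 400 bp setting misses a BTB peak well off the centre of a wide L(3)mbt peak. In all, 599 L(3)mbt peaks met a 2.2 peak (17.9%, 16.6 to 19.2%), 3.24-fold the random mean of 5.51% (permutation p = 0.001). For the long arms it was 13.7% (12.5 to 15.0%) against a random mean of 5.76%. The centres of L(3)mbt and BTB peaks that met lay a median of 114.5 bp apart (interquartile range 38.5 to 310 bp), against 564 bp for random placements (permutation p = 0.001). The share of L(3)mbt peaks with BTB was 39.1% (37.5 to 40.8%) when centres within 200 bp were required. The share with 2.2 was 7.28% (6.13 to 8.62%) when the upper 50% of each list by score was used. Both remained above their random means, which were 2.02% and 3.67%. The fold over random placements depended on the setting and ran from 7.29 to 35.4 for 2.2 with BTB, from 4.51 to 19.3 for L(3)mbt with BTB, and from 1.98 to 17.1 for L(3)mbt with 2.2.

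**Figure D1:**
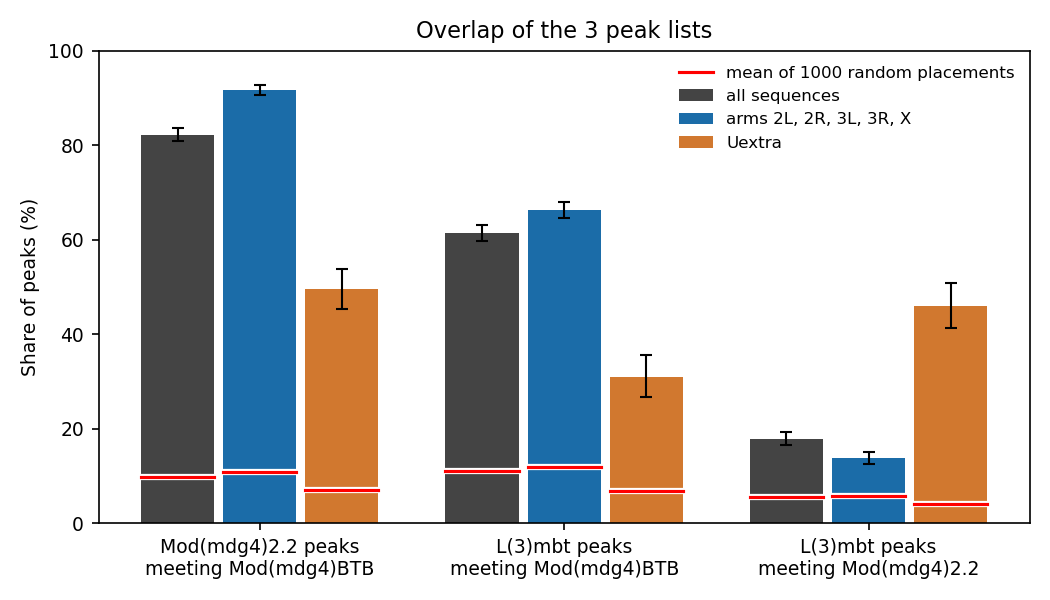
Share of peaks (%) that met a peak of the other list by at least 1 bp, for all sequences (grey), the 5 long arms (blue) and Uextra (orange). Bars are observed shares with 95% Wilson intervals and red lines the mean of 1000 random placements. The 2.2 peaks met BTB in 91.8% of cases on the long arms, and L(3)mbt met 2.2 in 13.7% there and in 46.0% on Uextra.

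The third comparison asked whether L(3)mbt sits at the same Mod(mdg4) sites as the 2.2 isoform. It was found less often at the BTB peaks that hold 2.2. L(3)mbt met 1816 of the 5088 BTB peaks without 2.2 (35.7%, 34.4 to 37.0%) and 520 of the 2533 with 2.2 (20.5%, 19.0 to 22.1%), an odds ratio of 0.465 (0.415 to 0.521; two-sided Fisher's exact test, p = 2.49e-43). If both proteins were spread over the BTB peaks independently, 776 peaks with both would have been counted. Within the long arms the shares were 44.2% (42.7 to 45.8%) and 19.9% (18.3 to 21.6%), with an odds ratio of 0.313 (0.276 to 0.354; Fisher's exact test, p = 1.81e-85) and 436 peaks with both against 779.5 under independence. The odds ratio was 0.255 on 2L, 0.323 on 2R, 0.355 on 3L, 0.286 on 3R and 0.337 on X, and its upper bound was at most 0.463 on each (Fisher's exact test, largest adjusted p = 8.24e-16). On Uextra the direction was opposite, with L(3)mbt at 26.98% of the BTB peaks with 2.2 (22.10 to 32.48%) and 6.42% of those without (5.02 to 8.18%), an odds ratio of 5.37 (3.64 to 7.95; Fisher's exact test, p = 1.57e-18). The odds ratio over all sequences was 0.710 (0.612 to 0.823) with centres within 200 bp and 0.211 (0.167 to 0.264) with the upper 50% of each list, a filter that removes more of the 2.2 peaks shared with L(3)mbt than of the others. Fisher's exact test takes the peaks as independent, but neighbouring BTB sites tended to agree in 2.2 and L(3)mbt status, as given below. Its intervals are thus likely too narrow and its p-values too small. All these ratios are among BTB peaks only. Among all L(3)mbt peaks on the long arms, 13.7% met 2.2, above the random mean of 5.76%. Of these 396 peaks, 387 also met BTB (97.7%), so this overlap lay almost wholly at BTB peaks. The BTB antibody recognises all isoforms, so BTB peaks without 2.2 may hold other isoforms. A ratio below 1 does not tell avoidance of 2.2 from a preference of L(3)mbt for those peaks.

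**Figure D2:**
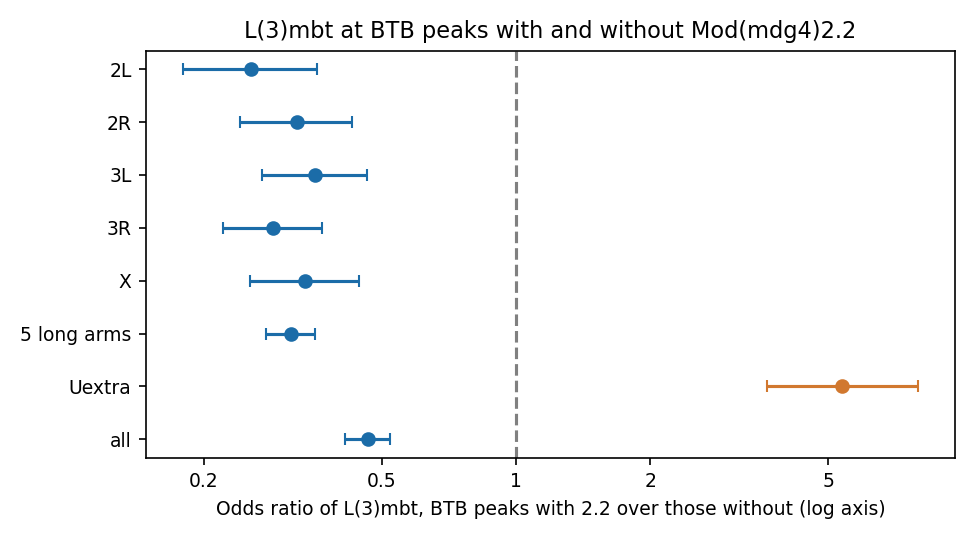
Odds ratio of an L(3)mbt peak at BTB peaks with 2.2 over BTB peaks without, on a log axis, with exact 95% intervals, for each long arm, the 5 long arms together, Uextra and all sequences. The dashed line marks 1. The long arms lie between 0.255 and 0.355, and Uextra at 5.37.

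Joined into sites, the 3 lists gave 6883 sites on the long arms. BTB alone held 2203 of them (32.0%), BTB with 2.2 held 1627 (23.6%), BTB with L(3)mbt held 1523 (22.1%), L(3)mbt alone held 966 (14.0%) and all 3 held 385 (5.59%). The 2.2 isoform alone held 172, and 2.2 with L(3)mbt but without BTB held 7 (0.102%). In U and Uextra the last class held 120 of 1835 sites (6.54%).

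**Figure D3:**
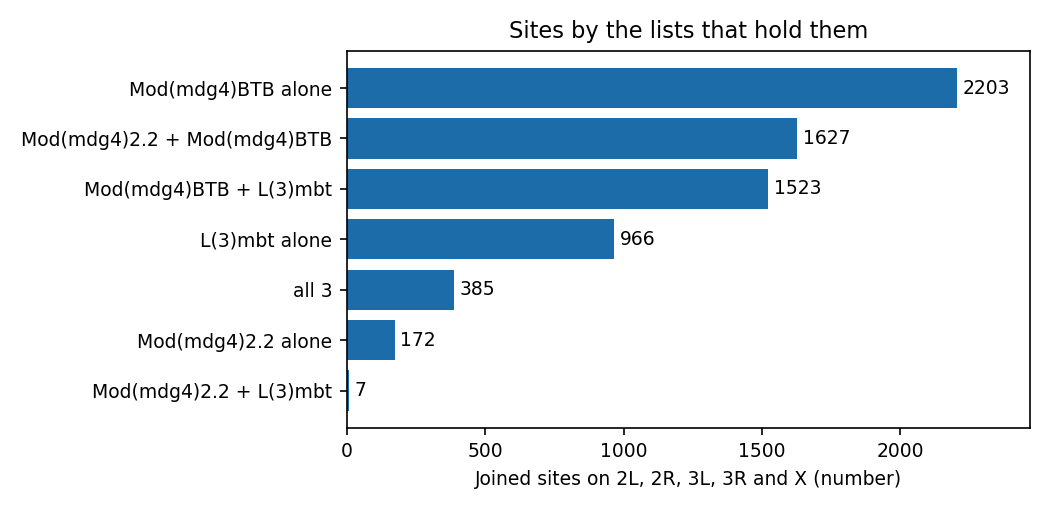
Number of joined sites on the arms 2L, 2R, 3L, 3R and X by the lists that held them. BTB alone (2203 sites) was the largest class, and 2.2 with L(3)mbt but without BTB (7 sites) the smallest.

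Over all sequences, 2.2 peaks that met both BTB and L(3)mbt ranked lower than those that met BTB without L(3)mbt. Among the 2.2 peaks with BTB, the 467 with L(3)mbt had a median score of 358 and the 1874 without it 1263, at median percentiles of 42.6 and 62.9 in the 2.2 list (permutation test, adjusted p = 1.2e-05). On Uextra, where 2.2 peaks score low in general, the median scores were 218 for 73 peaks with L(3)mbt and 173 for 198 without, and this contrast was not tested. By score, L(3)mbt met 30.8% of the 2.2 peaks scoring 100 to 200 on the long arms (26.4 to 35.6%) and 13.4% of those at or above 3100 (11.1 to 16.1%). BTB peaks held by all 3 lists had a median percentile of 66.8 in the BTB list, those with 2.2 and no L(3)mbt 62.5, those with L(3)mbt and no 2.2 51.2, and those with neither 38.5. For the long arms alone these were 87.1, a median tied at the score ceiling, 66.5, 51.9 and 44.0. On the long arms, among peaks with 2.2, 50.5% of those with L(3)mbt and 37.7% of those without were at the score ceiling (odds ratio 1.68, 1.35 to 2.09; Fisher's exact test, adjusted p = 3.01e-06). Among peaks without 2.2 these shares were 28.4% and 23.2% (odds ratio 1.32, 1.14 to 1.52; Fisher's exact test, adjusted p = 0.000203). Both tests, adjusted over 4 contrasts, were added after seeing the data. The BTB peaks with L(3)mbt were also wider, with medians of 894.5 against 632.5 bp with 2.2, and 705 against 603 bp without 2.2. A wide peak meets L(3)mbt by 1 bp more easily, and these tests were not repeated at 400 bp. BTB peaks with L(3)mbt ranked above those without it by 7.12 percentile points (permutation test, adjusted p = 1.2e-05), but by 0.46 on the long arms (permutation test, adjusted p = 0.727). The 0.46 takes peaks with and without 2.2 together, and within each of these classes the difference on the long arms was larger, at 20.7 and 7.86 points. L(3)mbt peaks with BTB and 2.2 ranked below those with BTB and no 2.2 in the L(3)mbt list, at median percentiles of 53.6 and 58.5 (permutation test, adjusted p = 0.0378). This call did not hold on the long arms (permutation test, adjusted p = 0.139) or with peaks set to 400 bp (adjusted p = 0.146).

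**Figure D4:**
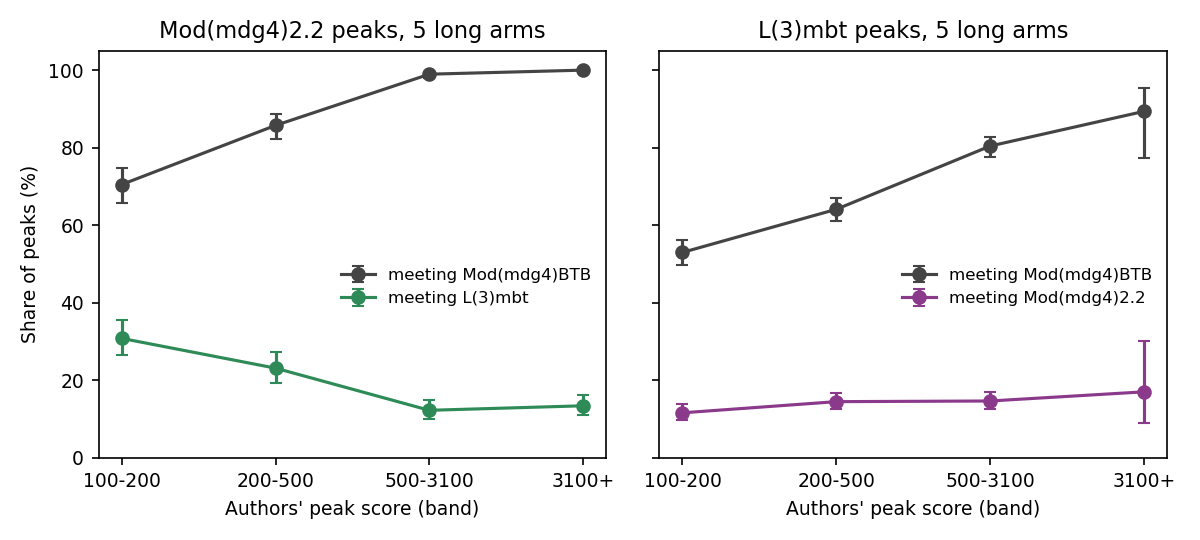
Share of peaks on the 5 long arms that met a peak of another list by at least 1 bp, by band of the authors' peak score, for 2.2 peaks (left) and L(3)mbt peaks (right). Points are shares and bars 95% Wilson intervals. BTB met 70.5% of the weakest 2.2 peaks and 53.0% of the weakest L(3)mbt peaks, and L(3)mbt met 30.8% of the weakest and 13.4% of the strongest 2.2 peaks.

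At the score ceiling, all 729 peaks of 2.2 met BTB (99.5 to 100%) and 96 met L(3)mbt (13.2%, 10.9 to 15.8%). Of the 1960 BTB peaks at the ceiling, 905 met 2.2 (46.2%, 44.0 to 48.4%) and 723 met L(3)mbt (36.9%, 34.8 to 39.0%). Of the 51 L(3)mbt peaks at the ceiling, 42 met BTB (82.4%, 69.7 to 90.4%) and 12 met 2.2 (23.5%, 14.0 to 36.8%). All these shares count an overlap of 1 bp, which a wide peak meets more easily. With peaks set to 400 bp, 30.9% of the 2.2 peaks with BTB and 8.31% of the 662 without were at the ceiling. Not every 2.2 peak at the ceiling met BTB by that setting, which misses a BTB peak well off the centre of a wide peak. For L(3)mbt these shares were 0.956% with BTB and 2.09% without. Peaks at the ceiling are tied, so the 10 taken by score in each list are examples in no order, and those of the L(3)mbt list that scored exactly 3100 were the first in genome order. Among the examples from the 2.2 list is chromosome X, 9107121 to 9108387, held by 2.2 and BTB. Those from the BTB list include 2R, 14653343 to 14654028, held by 2.2 and BTB. Those from the L(3)mbt list include 2L, 7825262 to 7828920, held by all 3 lists, and Uextra, 26844207 to 26845126, where L(3)mbt met 2.2 and no BTB peak. Of the BTB peaks held by all 3 lists, 2 reached the score ceiling in every list, at 2L, 21214679 to 21215637, and at 3R, 3710920 to 3713022. They were followed by 3R, 12623953 to 12624927, 3R, 7034337 to 7036341, and 3L, 505252 to 506595, where L(3)mbt scored 2441, 2293 and 1821. Sites with BTB and L(3)mbt but no 2.2 included 15 tied at the ceiling in both lists, the first in genome order at 2L, 6338173 to 6339641, and at 2R, 5439387 to 5442056. Sites with BTB and 2.2 but no L(3)mbt included 572 tied at the ceiling, the first in genome order at 2L, 65585 to 66193. Which genes lie at these positions was not analysed here.

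Peaks of each protein lay closer together than ones placed at random over whole sequences. Any parts where no peak can be called were included, which would lengthen the random distances. The median distance from a peak centre to the nearest of its own list was 7728 bp for L(3)mbt against a random mean of 15308 bp, 12683 bp for 2.2 against 19315 bp, and 5567 bp for BTB against 7137 bp (one-sided permutation tests, each p = 0.001, the smallest that 1000 placements can give).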

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

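Some tests were chosen only after the result was seen. They concern a deficit of control reads, sites enriched in every library, and unplaced sequence as the cause of lower ranks. Other values were added after seeing the data. These included the odds ratios over score bands, over joined peaks and for the upper 50% of each list on the long arms. They also included the 400 bp and 200 bp settings on the long arms and the BTB peaks at the ceiling, split by 2.2.

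The relation between L(3)mbt and 2.2 at BTB peaks was opposite in unplaced sequence and on the long arms. The odds ratio was 5.76 (3.95 to 8.44) in U and Uextra and 0.313 (0.276 to 0.354) on the long arms, a ratio of 18.5 between them (Woolf's 95% interval 12.6 to 27.1). Sites where L(3)mbt and 2.2 coincided without BTB were frequent in the former and nearly absent from the latter. Crowding of peaks spread evenly over Uextra is argued against, because 46.0% of the L(3)mbt peaks there met 2.2 and the highest of 1000 random placements gave 7.43%. The placements used all of Uextra, including any parts where no peak can be called, so crowding within a smaller part stays open. A deficit of control reads that raises all 3 libraries alike is argued against only as the sole source of these peaks. Of the L(3)mbt peaks with 2.2 on Uextra, the 73 with BTB ranked below the 119 without it in the L(3)mbt list. The difference was -39.4 points (bootstrap interval -53.7 to -25.5), where such a deficit acting alone needs the reverse. The 73 may include weak sites that do not come from a deficit, so a deficit behind the 119 stays open. A deficit that acts unequally on the libraries, repeated sequence that was recovered or aligned differently in the BTB library, and a real difference of heterochromatic sites remain open and were not tested. For the sites without BTB, a real difference would also need 2.2 to go undetected by the BTB antibody, which recognises all isoforms. Of the 2.2 peaks, 49.5% met BTB on Uextra and 91.8% on the long arms.

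On the long arms L(3)mbt was less frequent at the BTB peaks that hold 2.2. Unequal strength of the BTB peaks is argued against. Of the BTB peaks scoring 100 to 200, 17.0% met 2.2 and 31.0% L(3)mbt, and of those at the ceiling 46.7% and 37.9%. Strength alone would thus raise the ratio, so pooling over 4 bands of BTB score could hardly have brought it to 1. The pooled ratio was 0.278 (0.245 to 0.316). Several BTB peaks under 1 wide 2.2 peak are argued against by the odds ratio after joining BTB peaks less than 1000 bp apart, 0.309 (0.271 to 0.352). Peaks near the calling threshold stay open: the upper 50% of each list gave 0.179 (0.141 to 0.224), but 2.2 peaks shared with L(3)mbt ranked lower (median percentiles of 46.1 and 67.0), so the filter removes them first and lowers the ratio by itself. On the long arms the ratio was nearer 1 under 2 other definitions of sharing, 0.502 (0.425 to 0.591) with centres within 200 bp and 0.403 (0.348 to 0.465) with peaks set to 400 bp, and differences between antibodies or cultures remain open with 1 library each. The ratio is among BTB peaks only, so avoidance of 2.2 was not separated from a preference of L(3)mbt for BTB peaks of other isoforms.

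Over all sequences the 2.2 peaks with BTB that were shared with L(3)mbt ranked lower in the 2.2 list than the unshared ones. The median percentiles were 42.6 and 62.9. Unplaced sequence is argued against as the whole cause, since the difference on the long arms alone was -20.9 points (permutation p = 1e-05, the smallest 100000 resamples can give). Sites enriched in every library stay open: in the L(3)mbt list on the long arms the difference between peaks with and without 2.2 was -4.34 points, with a bootstrap interval from -8.20 to 0.69 that includes a small rise. In the BTB list on the long arms, 50.5% of the peaks with 2.2 and L(3)mbt and 37.7% of those with 2.2 and no L(3)mbt were at the score ceiling (Fisher's exact test, adjusted p = 3.01e-06), which does not decide it. No biological explanation was tested.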

How the results depend on the processing

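Of 57 values recomputed for tested results, 54 kept their direction and side of the threshold. The 3 others kept the direction and lost the call. Between BTB peaks with and without L(3)mbt the difference in median rank was 0.46 points on the long arms. Taken apart by 2.2 over all sequences it was 4.36 points with 2.2 and 12.7 without, and on the long arms 20.7 and 7.86, where the 20.7 rests on a median tied at the score ceiling. Between L(3)mbt peaks (with BTB) with and without 2.2 it was -4.34 points on the long arms and -3.82 points with peaks set to 400 bp. The cause was not tested. Between L(3)mbt peaks with and without BTB it was 18.4 points, and 6.996 with peaks set to 400 bp. Over the alternatives, the share of 2.2 peaks with BTB ran from 68.6 to 91.8%, that of L(3)mbt with BTB from 39.1 to 66.3%, that of L(3)mbt with 2.2 from 7.28 to 17.9%, and the odds ratio from 0.179 to 0.710. With placements shifted by 5 to 50 kb the folds over random were 7.29, 4.51 and 2.70 in that order of pairs. The odds ratio on the long arms with centres within 200 bp was 0.502, and the 4 settings that combine the long arms with another choice, the joined peaks, the score bands, the spacing on the long arms, the ranks at 400 bp and the BTB peaks taken apart by 2.2 were added after seeing the data. By covered length instead of number, U and Uextra held 17.4% of the 2.2 list, 14.3% of the BTB list and 8.60% of the L(3)mbt list. Other settings for start sites, gene lists and motifs were not run, since no annotation of the build of the files was used. Leaving out a replicate was not possible with 1 library per antibody. No paired analysis was possible because each antibody has 1 library. Depth is unknown, so a site without a peak may be a site below the threshold of that list. On the long arms BTB met 270 of 383 2.2 peaks scoring 100 to 200, and 715 of 715 at the ceiling, counting an overlap of 1 bp.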

Other observations

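The tests of runs were set out before their results, and the windows and stretches named here were chosen after their values were seen. The 2 Mb of each long arm nearest the centromere held 10.2 peaks of 2.2 per Mb against 19.3 elsewhere on the arms, 31.4 against 53.7 of BTB, and 18.3 against 24.9 of L(3)mbt. Among 1189 windows of 100 kb on the long arms, 287 had no 2.2 peak, 294 no L(3)mbt peak and 50 no BTB peak. The densest BTB window was 3R, 12000001 to 12100000, with 27 BTB, 12 L(3)mbt and 4 2.2 peaks. The next, 2R from 15600001 to 15700000, had 21 BTB peaks and 1 of each other protein. The densest 2.2 window was 3L, 5900001 to 6000000, with 11 peaks of 2.2, 13 of BTB and 3 of L(3)mbt. The window 2L, 21400001 to 21500000, had 11 L(3)mbt peaks with 2 of BTB and 1 of 2.2. The longest stretch without an L(3)mbt peak ran over 963 kb of 3L, from 23272818 to 24235542, and the longest without 2.2 over 595 kb of 2R, from 160591 to 755458. How much of these stretches and of the parts nearest the centromere reads can be aligned to was not analysed.

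Not every site followed the main classes. On the long arms 966 of 2890 L(3)mbt peaks (33.4%, 31.7 to 35.2%) met neither Mod(mdg4) list, and their median percentile in the L(3)mbt list was 38.9. The 975 without BTB lay a median of 6610 bp from the nearest BTB centre. The 181 2.2 peaks without BTB had a median score of 172 against 1361 for those with it.

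A hypothesis written before its test was that sites of 1 kind occur in runs along an arm. BTB peaks on the long arms were joined into 5299 sites, and 62.1% of neighbouring sites agreed in whether they held 2.2, against a mean of 53.3% and a highest value of 56.0% over 10000 permutations within arms (permutation p = 0.0001, the smallest they can give). For L(3)mbt 61.5% agreed, against a mean of 54.3% and a highest of 56.6% (permutation p = 0.0001). Wide peaks that span neighbouring sites are argued against, because among pairs at least 5 kb apart and under no common peak 59.9% agreed for 2.2 and 60.3% for L(3)mbt, above the highest permutations of 56.3% and 57.2%. Runs may follow chromatin domains or regional differences in how well chromatin is recovered, and these were not separated.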
